A study of Mus musculus and Homo sapiens with 17 samples.

How the data were processed

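ChIP-seq peak lists were read for 15 libraries, 10 from whole brain of CD1 mice at postnatal day 1 and 5 from 293T-REx cells. Per the labels' protocols, chromatin was crosslinked with paraformaldehyde or formaldehyde, sonicated and immunoprecipitated, and the libraries were amplified by PCR after size selection. Reads had been aligned to mm9 or hg19, and Bowtie and SAMtools were used, per the submitters' processing notes, which give no versions for these. The rightmost peak ends on chromosome 1, 197068437 in brain and 249213248 in 293T-REx, were checked against these builds. Each file belonged to 1 library, so peaks had been called per library. The peak caller, its use of the inputs, the handling of duplicate tags and whether coordinates count from 0 or 1 are not given in the sources used here, and coordinates are printed as in the files.

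Each list had 8 columns. Per the file headers, they gave chromosome, start, end, mean position, tag counts on the plus and on the minus strand, an average enrichment and a p-value. A header stood in 7 of the deposited files. The other 8 were read in the same column order, which their values did not contradict. The deposited counts are whole tags inside each peak. The enrichment is the authors' ratio per peak, and what it is relative to is not stated in the file headers. The deposited p-value is also the authors' own. Every listed peak had at least 10 tags, an enrichment of at least 2.5 and a p-value of at most 0.00945, so weaker peaks are not represented. Enrichment was used only to describe, rank, filter or match peaks within a list. Tags in peaks are not library depth, and a list from a deeper library or a stronger antibody can be longer, which would raise every share that overlaps it.

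Peak width was computed as end minus start. Peaks were taken as overlapping when they shared at least 1 bp. Overlaps were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15 and checked with bedtools 2.31.1. Shares carry 95% exact Clopper-Pearson intervals (scipy 1.17.1), and differences of shares carry Newcombe intervals. Neighbouring peaks are not independent and peaks are not replicates, so these intervals cover counting error only and no p-value for a condition was computed. As a reference, AUTS2 peaks were shifted circularly along their chromosomes 1000 times. A stricter reference placed them within the merged regions of all lists of the source. These regions were joined end to end, so a placed peak could run across a junction into another region. Peaks of 2 classes were matched 1 to 1 on width, or on enrichment, with a 10% caliper and 1 fixed random seed. Intervals for matched peaks took the 2 shares as independent and did not use the pairing. Figures were drawn with matplotlib 3.10.9.

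The overlap code was tested on simulated lists of 4000 peaks, where observed and predicted shares differed by at most 0.439 percentage points. Newcombe intervals covered the true difference in 95.8% of 1000 draws. A simulated mark that depended on width alone gave a raw difference of 23.0 points and 0.982 points after width matching.

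Groups, comparisons and most alternatives were fixed before the data were examined. The alternatives were overlap of at least 50% of the query peak, its midpoint inside the other peak, the other list widened by 1 kb, the 50% of each list with the highest enrichment, autosomes only, the stricter placement, and matching on width or enrichment. Chosen after seeing the data were the use of enrichment as the authors' score, the caliper, the bins of width and enrichment, the direct comparison of RING1B peaks with AUTS2 alone and BMI1 alone, the width matching of P300 peaks and the matching restricted to RING1B peaks with H3K4me3. The peaks named were the 3 with the highest enrichment in each class, the form of the rule that had been fixed for lists without gene names.

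Gene lists had also been fixed for a count of promoters with each factor. They were not used, because the gene table at hand was of another mouse build (GRCm38.p6) and coordinates were not converted. The inputs and the RNA-seq data that the series' design mentions were not analysed here.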

Results

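Chromatin immunoprecipitation followed by sequencing (ChIP-seq) lists the genomic regions at which DNA bound by a protein, or wrapped on histones that carry a given mark, was enriched. It was applied to 17 samples, 11 from whole brain of CD1 mice at postnatal day 1 and 6 from 293T-REx, a human embryonic kidney line that expresses the tetracycline repressor. The panel centred on Polycomb repressive complex 1 (PRC1), a chromatin complex best known for gene repression, and on AUTS2, the product of a gene disrupted in some people with autism and other neurodevelopmental disorders. In brain, peak lists were read for 10 antibodies. They recognised AUTS2, RING1B (the ubiquitin ligase of PRC1, which places H2AK119ub1), BMI1 (a subunit of canonical PRC1), P300 (an acetyltransferase that places H3K27ac), RNA polymerase II (PolII) and 5 histone marks. In 293T-REx, 5 lists were read, namely HA-AUTS2 from a line that expressed tagged AUTS2, and PolII, H3K27ac, H3K4me3 and H3K36me3 from a mock line. The remaining 2 samples were inputs, for which no peak list was used here.

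Each antibody had 1 library per source, so no difference below has a replicate check, and the intervals cover counting error over peaks only. The brain lists held 5482 peaks for AUTS2, 16299 for RING1B, 2889 for BMI1, 2592 for P300, 26182 for PolII, 21152 for H3K27ac, 15281 for H3K4me3, 25946 for H3K36me3, 23512 for H3K27me3 and 20181 for H2AK119ub1. The 293T-REx lists held 5563 peaks for HA-AUTS2, 37655 for PolII, 32533 for H3K27ac, 15601 for H3K4me3 and 76538 for H3K36me3. Sequencing depth is unknown, since only tags inside peaks were listed. These came to 160438 tags for brain AUTS2, 137502 for HA-AUTS2, and up to 9737759 in brain and 17348080 in 293T-REx, both for H3K4me3. Regions are given by position in mm9 or hg19, without gene names, because no annotation of these builds was used here.

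The first comparison asked which marks and factors lay at AUTS2 sites in the newborn mouse brain. AUTS2 peaks overlapped PolII and the marks of active promoters and enhancers more often than the other lists, each at about 50% of peaks. PolII peaks overlapped 54.8% of the 5482 AUTS2 peaks (95% exact interval 53.5 to 56.2), H3K4me3, a mark of promoters, overlapped 51.3% (50.0 to 52.6), and H3K27ac, a mark of active promoters and enhancers, overlapped 50.5% (49.2 to 51.9). RING1B overlapped 13.5% (12.6 to 14.4) and P300 6.86% (6.20 to 7.56). The repressive marks were rarer than PolII, H3K4me3 and H3K27ac, with 9.03% (8.28 to 9.82) for H2AK119ub1 and 7.19% (6.52 to 7.90) for H3K27me3, the mark placed by Polycomb repressive complex 2. H3K36me3, found along the bodies of transcribed genes, overlapped 5.02% (4.45 to 5.63), and BMI1 2.68% (2.27 to 3.14). H3K27ac was at 48.1% with at least 50% of the AUTS2 peak covered and 47.9% with its midpoint. In the 50% of each list with the highest enrichment, PolII was at 68.3% and H3K27ac at 54.4%, while H3K4me3 was at 43.999%, H2AK119ub1 at 4.597%, H3K27me3 at 4.52%, H3K36me3 at 2.66% and BMI1 at 1.496%. This setting shortened the other lists as well, so a lower share need not mean fewer features at stronger AUTS2 peaks. Against the full H3K4me3 list, the 10% of AUTS2 peaks with the highest enrichment were at 96.9%.

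Every one of these shares lay above all of 1000 circular shifts of the AUTS2 peaks along their chromosomes. The excess over the mean shift was 40.6-fold for P300, 26.3-fold for H3K27ac, 24.9-fold for H3K4me3 and 22.3-fold for PolII. It was smaller for BMI1 (12.5-fold), RING1B (7.56-fold), H2AK119ub1 (5.72-fold), H3K27me3 (2.67-fold) and H3K36me3 (2.07-fold). When AUTS2 peaks were placed at random only within regions covered by some brain peak, P300 (2.92-fold), H3K27ac (2.00-fold), H3K4me3 (1.80-fold) and PolII (1.72-fold) stayed above that placement. RING1B (0.575-fold), H2AK119ub1 (0.464-fold), H3K27me3 (0.211-fold) and H3K36me3 (0.184-fold) fell below every such placement, and BMI1 (0.892-fold) lay within their range. Placed peaks could cross junctions between the joined regions, which can raise this reference and lower its folds. The size of that effect was not measured, so a fold below 1 here does not by itself show avoidance. With the other lists widened by 1 kb, the log2 excess over shifts fell from 5.34 to 4.37 for P300 and from 4.48 to 3.71 for PolII, and in the 50% of each list with the highest enrichment it was 6.08 and 5.65.

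**Figure D1:**
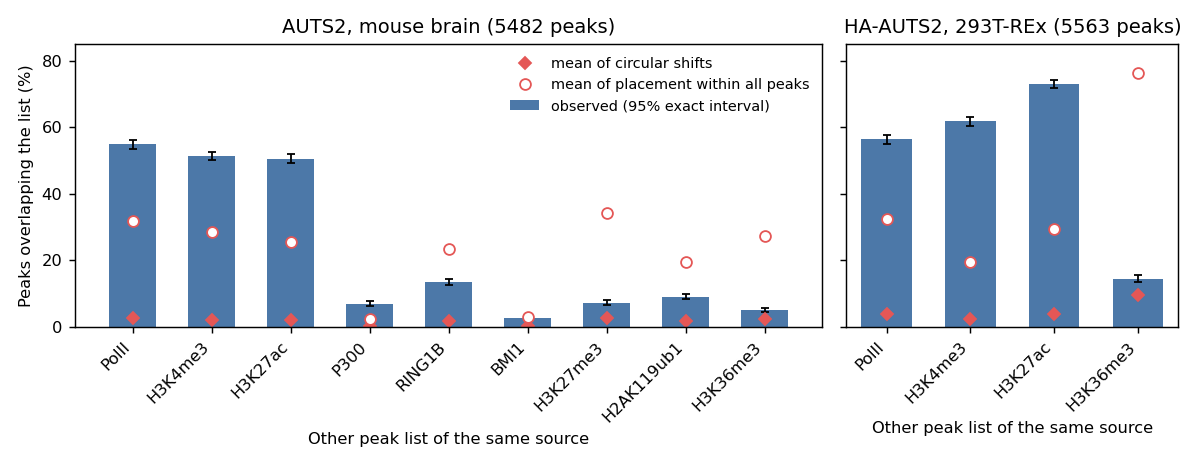
Share of AUTS2 peaks (vertical axis, percent) that overlapped each other peak list of the same source, for mouse brain on the left and 293T-REx on the right. Bars are observed shares with 95% exact intervals, filled diamonds the mean of circular shifts, and open circles the mean of placements within the regions covered by all peaks. In brain, the bars for PolII, H3K4me3, H3K27ac and P300 rise above both references, while those for RING1B, H3K27me3, H2AK119ub1 and H3K36me3 lie between them.

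The active features often overlapped the same AUTS2 peaks. Separate libraries of whole brain cannot show whether overlapping features shared the same cells, here or in the classes below. Of the 5482 brain peaks, 2490 (45.4%, 44.1 to 46.8) overlapped H3K4me3, H3K27ac and PolII together, and 2228 (40.6%, 39.3 to 42.0) overlapped none of these. Smaller classes had H3K27ac without H3K4me3 (243 peaks, 4.43%) or H3K4me3 without H3K27ac (285 peaks, 5.20%), and 173 peaks (3.16%) had H3K4me3 together with H3K27me3. Among the 2228, 1635 peaks (29.8% of all AUTS2 peaks, 28.6 to 31.1) overlapped no other brain list. The shares depended on peak strength, a split chosen after the overlaps had been seen. In the 549 peaks of lowest enrichment, 26.2% (22.6 to 30.1) overlapped H3K4me3, and in the 549 of highest enrichment 96.9% (95.1 to 98.2). PolII went from 31.3% to 97.6% and RING1B from 6.92% to 20.9% between the same groups, whereas H3K27me3 went from 9.11% to 1.64% and H3K36me3 from 7.10% to 0.364%.

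**Figure D2:**
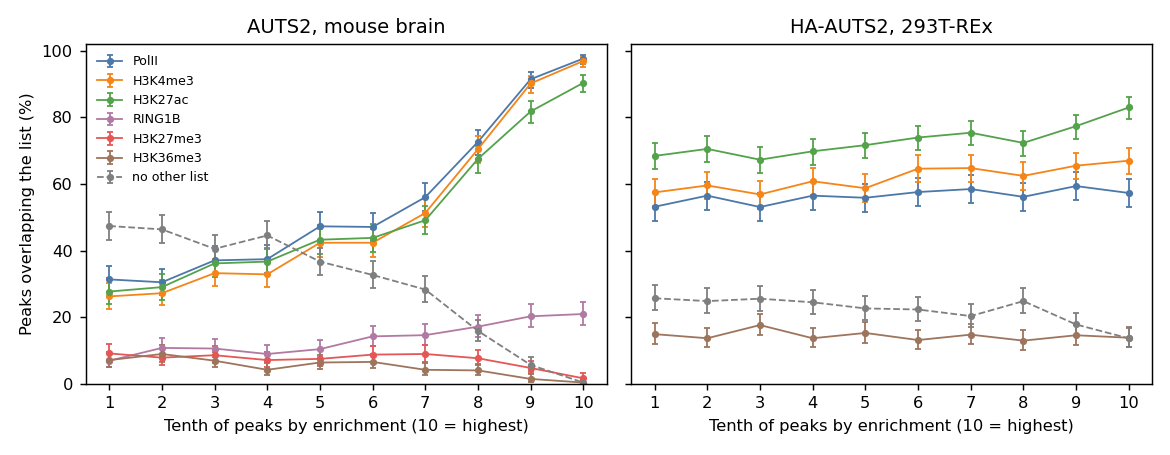
Share of AUTS2 peaks (vertical axis, percent) that overlapped each list, in 10 bins of peaks ordered by the authors' enrichment (horizontal axis, 10 the highest), for brain on the left and 293T-REx on the right. Points are shares with 95% exact intervals, and the dashed line gives peaks that overlapped no other list. In brain H3K4me3 climbs from 26.2% to 96.9%, and in 293T-REx from 57.5% to 67.0%. The bins span unlike ranges, and the highest had a median enrichment of 13.0 in brain and 4.97 in 293T-REx.

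The 3 brain AUTS2 peaks of highest enrichment illustrate the common class. They lay on chromosome 1 from 187027635 to 187028618 (mm9, enrichment 86.8, 414 tags), on chromosome 16 from 4474836 to 4475729 (enrichment 68.8, 254 tags) and on chromosome 18 from 80403031 to 80403896 (enrichment 56.2, 386 tags). All 3 overlapped PolII, H3K27ac and H3K4me3 peaks, none overlapped RING1B, and the peak on chromosome 1 also overlapped BMI1.

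The second comparison asked whether RING1B sites with AUTS2 differed from other RING1B sites. RING1B peaks with AUTS2 carried the active features far more often than those without it. H3K4me3 overlapped 91.4% of 723 RING1B peaks with AUTS2 and 20.4% of 15576 without, a difference of 71.1 percentage points (Newcombe 95% interval 68.7 to 73.0). PolII overlapped 89.6% against 15.0% (difference 74.7, 72.2 to 76.8), H3K27ac 85.2% against 15.1% (70.1, 67.3 to 72.6) and P300 16.3% against 1.67% (14.7, 12.1 to 17.5). Each of these differences had the same sign on 20 of 20 chromosomes. H3K36me3 overlapped 5.67% against 2.69% (2.98, 1.49 to 4.93), with the same sign on 13 of 20 chromosomes. Its interval included 0 at 50% coverage (-0.0251), with midpoints (-0.828) and in the 50% of each list with the highest enrichment (1.12), and the difference was 6.62 (4.64 to 8.97) with the other lists widened by 1 kb.

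The repressive marks depended on the width of the RING1B peaks. Taken as listed, RING1B peaks with AUTS2 overlapped H3K27me3 in 26.0% against 17.3% (difference 8.67, 5.55 to 12.04) and H2AK119ub1 in 23.4% against 12.1% (11.3, 8.31 to 14.6). Peaks with AUTS2 were wider, with a median of 3171 bp against 728 bp. In 723 pairs matched on width, H3K27me3 was less frequent with AUTS2 than without it, at 26.0% against 48.1% (difference -22.1, -26.9 to -17.2), and so was H2AK119ub1, at 23.4% against 32.8% (-9.41, -14.0 to -4.78). The gap varied with width. For H3K27me3 it was 2.33% against 3.14% up to 1 kb, 42.0% against 79.2% over 4 and up to 8 kb, and 89.1% against 96.6% over 8 kb. Over 8 kb H2AK119ub1 was at 84.4% against 85.7%. The active features stayed more frequent in these pairs, by 29.5 points (25.3 to 33.5) for H3K4me3, 40.1 (35.5 to 44.4) for H3K27ac, 47.2 (42.8 to 51.3) for PolII and 10.1 (6.88 to 13.4) for P300. In the 50% of each list with the highest enrichment, the differences were -0.0118 (-4.65 to 5.41) for H3K27me3, 5.03 (0.806 to 10.1) for H2AK119ub1 and 8.72 (5.62 to 12.9) for P300. Pairs matched on width that all had H3K4me3, added after seeing the data, gave 19.8 (15.7 to 23.9) for H3K27ac and 26.5 (22.7 to 30.3) for PolII.

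**Figure D3:**
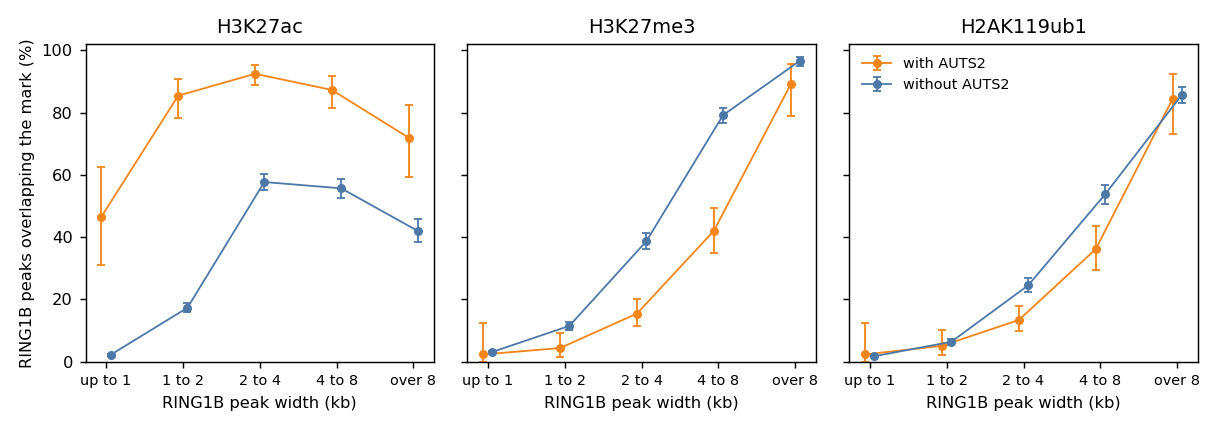
Share of brain RING1B peaks (vertical axis, percent) that overlapped H3K27ac, H3K27me3 or H2AK119ub1, by RING1B peak width (horizontal axis, kb), with AUTS2 in orange and without it in blue. Points are shares with 95% exact intervals. Among peaks over 2 and up to 4 kb wide, H3K27ac reached 92.4% with AUTS2 and 57.7% without, and H3K27me3 15.5% with AUTS2 and 38.6% without.

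The third comparison used BMI1 as the marker of canonical PRC1. Only 1335 of 2889 BMI1 peaks (46.2%, 44.4 to 48.0) overlapped RING1B, so the BMI1 list was an imperfect marker of PRC1 form. RING1B peaks with BMI1 carried the repressive marks more often than those without it, with H3K27me3 at 75.8% of 895 peaks against 14.3% of 15404 peaks without BMI1 (difference 61.4, 58.4 to 64.2) and H2AK119ub1 at 66.5% against 9.45% (57.0, 53.8 to 60.1). Active features were also more frequent with BMI1, at 78.5% against 20.3% for H3K4me3, 51.5% against 16.3% for H3K27ac, 47.5% against 16.6% for PolII and 10.2% against 1.86% for P300. H3K36me3 did not differ detectably (3.13% against 2.80%, difference 0.324, -0.669 to 1.70). RING1B peaks with BMI1 were wide, with a median of 7332 bp against 719 bp. In 724 width-matched pairs the intervals for H3K27me3 (4.14, -0.657 to 8.92), H3K27ac (2.90, -2.22 to 7.997), PolII (2.07, -3.07 to 7.20) and P300 (2.76, -0.0219 to 5.58) all included 0. Those for H2AK119ub1 (9.81, 4.67 to 14.9) and H3K4me3 (9.94, 5.64 to 14.2) did not. In the 50% of each list with the highest enrichment, the active differences were smaller than as listed, at 15.6 for H3K4me3, 14.03 for H3K27ac, 11.07 for PolII and 3.21 for P300. The repressive differences in that setting were 65.3 (61.7 to 68.5) for H3K27me3 and 57.3 (53.1 to 61.3) for H2AK119ub1. At 50% coverage of the RING1B peak, which left 70 peaks with BMI1, the differences were 22.8 (12.4 to 34.5) for H3K27me3, 23.5 (14.3 to 35.0) for H2AK119ub1 and 28.7 (17.7 to 40.4) for H3K4me3. With midpoints they were 55.2 (50.3 to 59.6) for H3K27me3, 45.4 (40.4 to 50.4) for H2AK119ub1, 20.1 for PolII and 1.99 for P300.

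By both factors, 627 RING1B peaks had AUTS2 alone, 799 BMI1 alone, 96 both and 14777 neither. Independent placement over RING1B peaks would give 39.7 with both, but in the 723 width-matched pairs BMI1 overlapped 13.3% of peaks with AUTS2 and 14.2% of those without (difference -0.968, -4.53 to 2.59). That check and the direct comparison of the single classes were chosen after the data had been seen. The 627 peaks with AUTS2 alone exceeded the 799 with BMI1 alone in PolII (90.1% against 42.8%, difference 47.3, 43.0 to 51.3) and in H3K27ac (85.2% against 47.4%, difference 37.7, 33.2 to 42.0). They fell short in H3K27me3 (23.1% against 79.5%, difference -56.3, -60.5 to -51.8) and H2AK119ub1 (20.3% against 69.2%, difference -49.0, -53.2 to -44.3). H3K4me3 was frequent in both (91.2% against 76.8%, difference 14.4), and this difference was 6.47 at matched width and 40.2 in the 50% of each list with the highest enrichment. In 371 width-matched pairs the directions held, with 35.3 points (29.1 to 41.1) for PolII, 23.2 (16.9 to 29.2) for H3K27ac, -27.0 (-33.6 to -19.9) for H3K27me3 and -16.4 (-23.1 to -9.53) for H2AK119ub1. At 50% coverage, with 116 and 67 peaks in the classes, the differences were -37.1 for H3K27me3, -29.0 for H2AK119ub1 and 42.3 for H3K4me3. The 96 peaks with both factors had H3K27ac in 85.4% (76.7 to 91.8) and H3K27me3 in 44.8% (34.6 to 55.3).

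**Figure D4:**
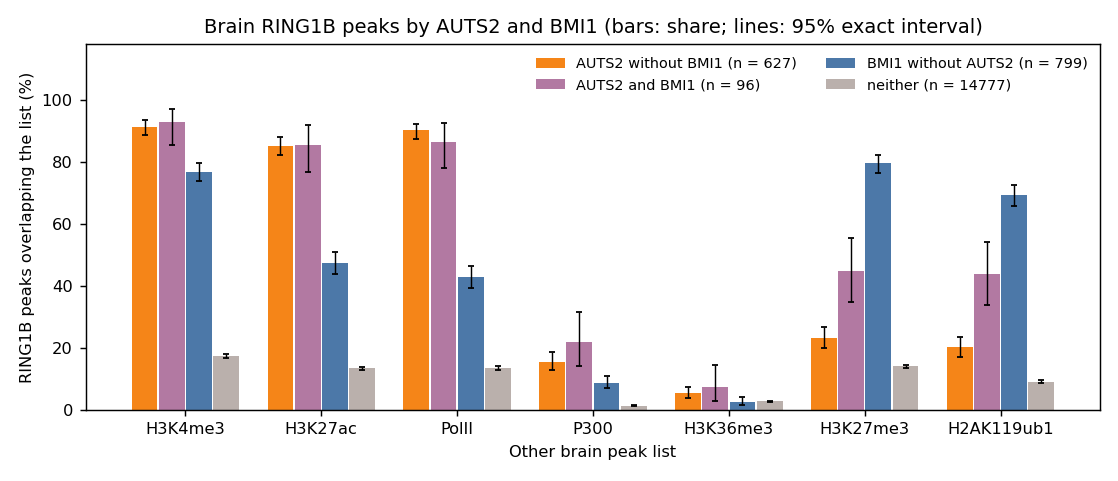
Share of brain RING1B peaks (vertical axis, percent) that overlapped each other list (horizontal axis), in 4 classes by AUTS2 and BMI1. Bars are shares and lines 95% exact intervals. H3K27ac reached 85.2% in peaks with AUTS2 alone and 47.4% in those with BMI1 alone, and H3K27me3 23.1% and 79.5%.

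Among RING1B peaks with AUTS2 alone, the 3 of highest enrichment lay on chromosome 2 from 147177565 to 147194409 (mm9, enrichment 8.95), chromosome 13 from 53565895 to 53573340 (8.77) and chromosome 5 from 145726358 to 145727121 (5.93). The peaks on chromosomes 2 and 13 overlapped H3K27me3 and H2AK119ub1, unlike most of their class, and the peak on chromosome 5 overlapped PolII and H3K4me3. With BMI1 alone, the strongest lay on chromosome 9 from 71062116 to 71069409 (enrichment 19.03), chromosome 3 from 96291149 to 96292199 (18.1) and chromosome 6 from 83017196 to 83025276 (16.7), each with H3K27me3 and none with PolII. With both factors they lay on chromosome 3 from 66769502 to 66793614 (13.6), chromosome 9 from 62977655 to 63001826 (13.4) and chromosome 2 from 28760083 to 28776864 (12.5), all with H3K27me3 and H2AK119ub1. With neither factor they lay on chromosome 9 from 44689425 to 44690340 (17.7), chromosome 12 from 85907720 to 85917228 (16.5) and chromosome 7 from 149843526 to 149852277 (13.7). The first of these overlapped PolII, H3K27ac and H3K4me3, and the others H3K27me3 and H2AK119ub1.

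The fourth comparison divided AUTS2 peaks by RING1B. AUTS2 peaks with RING1B carried both active and repressive features more often than those without it. H3K4me3 overlapped 88.6% of 739 peaks with RING1B and 45.5% of 4743 without (difference 43.2, 40.3 to 45.7), PolII 86.7% against 49.9% (36.9, 33.9 to 39.5), H3K27ac 81.1% against 45.8% (35.3, 32.0 to 38.3) and P300 13.7% against 5.80% (7.87, 5.47 to 10.6). H3K27me3 overlapped 18.8% against 5.38% (13.4, 10.7 to 16.5) and H2AK119ub1 15.3% against 8.05% (7.24, 4.69 to 10.1). H3K36me3 was the exception, at 1.49% against 5.57% (-4.08, -5.03 to -2.77). AUTS2 peaks with RING1B were also stronger, with a median enrichment of 3.74 against 3.19. In the 50% of each list with the highest enrichment, the differences were 28.6 (22.5 to 34.1) for H3K4me3 and 21.04 (16.2 to 24.98) for PolII, and the intervals for P300 and H3K36me3 included 0. The H2AK119ub1 difference was 4.57 at 50% coverage and 4.59 with midpoints.

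The fifth comparison divided P300 peaks by AUTS2. P300 peaks with AUTS2 were mostly in active chromatin, and those without it less often so. PolII overlapped 92.0% of 377 P300 peaks with AUTS2 and 37.5% of 2215 without (difference 54.5, 50.8 to 57.6), H3K4me3 89.9% against 35.6% (54.3, 50.3 to 57.6) and H3K27ac 90.5% against 37.1% (53.4, 49.4 to 56.6). H3K27me3 was less frequent with AUTS2, at 5.31% against 11.8% (-6.52, -8.85 to -3.49), as were H2AK119ub1 (6.90% against 11.2%, difference -4.30, -6.85 to -1.04) and H3K36me3 (3.71% against 7.13%, difference -3.42, -5.30 to -0.799). The H3K36me3 interval included 0 under 3 of the alternatives tried, and the H2AK119ub1 interval in the top 50% of each list, while width matching gave -8.22 (-12.7 to -3.78) for H2AK119ub1.

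The sixth comparison asked the first question of HA-AUTS2 in 293T-REx. Tagged AUTS2 in these kidney cells also overlapped active marks most often. Of its 5563 peaks, 72.9% (71.8 to 74.1) overlapped H3K27ac, 61.7% (60.5 to 63.0) H3K4me3 and 56.4% (55.1 to 57.7) PolII, which were 19.7-fold, 28.3-fold and 14.5-fold over the mean of circular shifts. H3K36me3 overlapped 14.4% (13.5 to 15.4), 1.52-fold over shifts, and 27.3% (log2 fold 1.22) when widened by 1 kb, 8.48% at 50% coverage and 9.45% in the top 50% of each list. H3K4me3, H3K27ac and PolII occurred together at 2968 peaks (53.4%), while 1235 (22.2%) overlapped none of the lists read. Placement within all 293T-REx peaks, with the same limit at junctions, left the 3 active lists above that reference and put H3K36me3 below it (0.189-fold). With at least 50% of the HA-AUTS2 peak covered, or its midpoint used, H3K36me3 no longer lay outside all shifts. The 3 peaks of highest enrichment lay on chromosome 7 from 135401206 to 135402080 (hg19, enrichment 11.6, 38 tags), chromosome 5 from 91887617 to 91888762 (10.3, 50 tags) and chromosome 8 from 37336601 to 37337164 (10.2, 30 tags). All 3 overlapped H3K27ac, the peak on chromosome 5 also overlapped H3K4me3, and none overlapped PolII. From the lowest to the highest of 10 bins by enrichment, the PolII share of HA-AUTS2 peaks went from 53.1% to 57.3%. H3K27ac went from 68.4% to 82.9%, H3K4me3 from 57.5% to 67.0% and H3K36me3 from 14.9% to 13.8%. In brain the PolII share went from 31.3% to 97.6%. These bins span unlike ranges, since the highest had a median enrichment of 13.0 in brain and 4.97 in 293T-REx. The eighth brain bin, with a median of 4.40, had PolII at 72.6%.

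The last comparison set the sources side by side. Active histone marks covered a smaller share of AUTS2 peaks in brain than in 293T-REx, by -22.4 points (-24.2 to -20.6) for H3K27ac and -10.5 (-12.3 to -8.61) for H3K4me3. H3K36me3 differed by -9.42 points (-10.5 to -8.33), and PolII by -1.54 (-3.39 to 0.315), an interval that included 0. In the 50% of each list with the highest enrichment the PolII share was higher in brain, by 19.1 points (16.6 to 21.7), whereas it was lower with lists widened by 1 kb (-2.18, -4.02 to -0.337) and on autosomes (-3.13, -5.01 to -1.25). The top 50% also gave -11.8 for H3K27ac and -6.86 for H3K4me3, and H3K36me3 was -4.16 at 50% coverage, -4.14 with midpoints and -19.95 with widened lists. The direction depended on the measure. As folds over the mean of circular shifts, brain was higher for H3K27ac (26.3 against 19.7), PolII (22.3 against 14.5) and H3K36me3 (2.07 against 1.52). For H3K4me3 the fold was lower in brain, at 24.9 against 28.3. Species, antibody, AUTS2 expression and the lengths of the other lists all differed between the sources.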

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

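The check of wide peaks was chosen after the strand shares had been seen.

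Strand counts entered no comparison above. In both H3K4me3 lists they were unequal, with 55.2% of tags on the plus strand in brain and 58.9% in 293T-REx, while the 13 other lists lay between 50.2% and 51.8%. Loss of minus-strand tags at peak edges would be diluted in wide peaks, but H3K4me3 peaks over 5 kb wide still had 55.3% in brain and 59.9% in 293T-REx, which argues against it. Loss of tags from 1 strand where they are dense stays open and may contribute, since the share in the 10% of peaks with the lowest tag density was 50.97% in brain and 50.96% in 293T-REx and rose to 57.5% and 61.8% in the densest 10%. How duplicate tags were removed is not given in the sources used here, and no biological explanation was tested.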

How the results depend on the processing

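Of 315 alternative values for 51 differences and folds, 275 kept their direction and side of the threshold (an interval that excludes 0, or a share outside all shifts), 16 lost the threshold, 2 gained it and 22 changed direction. Matching on enrichment moved none of 7 results outside its interval, so it says little about them. Alternatives marked as added were chosen after seeing the data. Matching on width removed the width difference between classes but did not establish it as the cause. The causes of the other changes were not tested.

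Placement within all peaks gave log2 folds of -0.80 for brain AUTS2 at RING1B, -0.17 at BMI1, -2.25 at H3K27me3, -1.11 at H2AK119ub1 and -2.44 at H3K36me3, and -2.40 for HA-AUTS2 at H3K36me3. Placed peaks that crossed junctions between joined regions can have lowered these values.

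Width matching gave, for RING1B with minus without AUTS2, -22.1 points for H3K27me3 and -9.41 for H2AK119ub1 (added, with H3K4me3 only, -23.4 and -13.0). With minus without BMI1 it gave 2.90 for H3K27ac, 2.07 for PolII, 2.76 for P300, 4.14 for H3K27me3 and -1.10 for H3K36me3, whose interval included 0 in every setting. For P300 peaks by AUTS2 (added) it gave -1.59 for H3K36me3.

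At 50% coverage, which also redefines the classes and keeps far fewer RING1B peaks with AUTS2, HA-AUTS2 at H3K36me3 had a log2 fold of 0.10. RING1B by AUTS2 gave -0.0251 for H3K36me3, -12.9 for H3K27me3 and -4.33 for H2AK119ub1, and by BMI1 1.00 for P300. AUTS2 alone minus BMI1 alone (added) gave 6.27 for P300 and -1.26 for H3K36me3.

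With midpoints, which also define the classes, the log2 fold was 0.12 for HA-AUTS2 at H3K36me3. RING1B by AUTS2 gave -0.828 for H3K36me3, -7.81 for H3K27me3 and -1.52 for H2AK119ub1, by BMI1 -1.01 for H3K36me3, and AUTS2 alone minus BMI1 alone (added) 0.191 for H3K36me3.

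Taking the top 50% of each list also shortened the other lists, so a peak whose only partner was weaker counted as without it. In this setting, RING1B by AUTS2 gave 1.12 for H3K36me3 and -0.0118 for H3K27me3, and by BMI1 -0.809 for H3K36me3. AUTS2 by RING1B gave 2.67 for P300 and -1.71 for H3K36me3, and P300 by AUTS2 -2.36 for H3K36me3 and -1.63 for H2AK119ub1. Brain minus 293T-REx was 19.1 for PolII, against -2.18 with lists widened by 1 kb and -3.13 on autosomes. Widening gave -1.36 for H3K36me3 at P300 by AUTS2.

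Of 65 alternative shares, 43 left the interval of their main value. The gene-list alternatives were not run, for lack of an annotation of the builds. No analysis of paired samples was possible because each antibody had 1 library per source. Depth is unknown, so a site outside a list is not shown to lack the factor or mark.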

Other observations

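The comparisons of peak strength, peak position, wide RING1B peaks and the X chromosome, and the split of AUTS2 peaks by enrichment, were chosen after the data had been seen. The tests of RING1B width were set once the width-matched differences were known, but before their own values were.

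Peaks shared with AUTS2 had higher median enrichment in every other brain list except BMI1, active and repressive alike. Brain PolII peaks with AUTS2 had a median enrichment of 8.89 (2967 peaks) against 3.697 without (23215), and 8.89 against 4.07 in 2965 width-matched pairs. H3K27ac peaks had 5.22 with AUTS2 against 3.57 without, and H3K4me3 peaks 14.6 against 12.5, or 14.6 against 13.8 at matched width. H3K27me3 peaks had 4.09 against 3.19, or 4.09 against 3.71 at matched width, and H3K36me3 peaks 3.503 against 3.11. PolII peaks were also stronger with P300 (8.02 against 3.86) and with BMI1 (6.45 against 3.90). In 293T-REx, PolII peaks with HA-AUTS2 had 6.41 against 3.52, and H3K4me3 peaks 10.9 against 7.69. With BMI1, H3K27me3 peaks had 9.003 against 3.16, or 7.87 against 4.74 at matched width, and RING1B peaks 4.67 against 2.83, or 3.86 against 2.95. AUTS2 midpoints fell in the central 50% of the peak around them in 79.2% of H3K4me3 cases and 78.5% of PolII cases, against 55.6% (50.1 to 61.0) for H3K27me3. H3K27ac was at 75.8%, while H2AK119ub1 (55.4%), BMI1 (54.3%) and H3K36me3 (57.9%) were near H3K27me3. RING1B (69.4%, 65.9 to 72.8) and P300 (69.0%, 63.6 to 74.1) lay between these groups, so the values did not fully separate active from Polycomb features.

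RING1B formed some very wide domains. The 4 widest peaks, named outside the fixed rule, lay on chromosome 6 from 52099494 to 52228973 (mm9, 129479 bp), chromosome 15 from 102734418 to 102848663, chromosome 11 from 96121123 to 96221307 and chromosome 2 from 74485328 to 74581594. All 4 overlapped H3K27me3, H2AK119ub1 and BMI1, and none overlapped AUTS2. Of the 777 RING1B peaks over 8 kb wide, 96.0% overlapped H3K27me3, 53.5% BMI1 and 8.24% AUTS2, against 17.7%, 5.49% and 4.44% of all RING1B peaks. Active features were also more frequent there, with 72.7% against 23.5% for H3K4me3, 44.4% against 18.2% for H3K27ac, 40.7% against 18.3% for PolII and 9.91% against 2.32% for P300. All RING1B peaks had a median width of 759 bp, a smaller target. Against peaks over 4 and up to 8 kb, those over 8 kb without AUTS2 had less H3K4me3 (71.4% against 83.2%), H3K27ac (41.9% against 55.7%) and PolII (37.6% against 49.5%). P300 was higher (8.98% against 6.06%), and peaks with AUTS2 gave the same 4 directions. At the other end, 10589 RING1B peaks (65.0%) overlapped no other brain list, with a median width of 578 bp. The X chromosome held 8.17% of H3K27me3 peaks (1922 of 23512) and 4.79% of RING1B peaks, but 1.02% of H2AK119ub1 peaks and 1.28% of AUTS2 peaks. As shares of covered sequence these were 5.05%, 2.36%, 0.812% and 1.09%. Low shares of peaks were not particular to AUTS2 and H2AK119ub1. The other brain lists had 0.771% (H3K36me3), 0.831% (BMI1), 1.54% (P300), 1.92% (H3K27ac), 2.18% (PolII) and 3.82% (H3K4me3). In 293T-REx the X chromosome held 6.09% of HA-AUTS2 peaks, and from 3.33% (H3K36me3) to 4.17% (H3K4me3) of the other lists.

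RING1B peaks with AUTS2 overlapped H3K27me3 more often as listed and less often at matched width. A larger target in wide peaks stays open and may account for the excess as listed, since the difference was -22.1 points at matched width. With class and mark both read at the RING1B midpoint it was -7.81 (-10.3 to -4.34). AUTS2 peaks had a median width of 692 bp, so requiring one at the midpoint can favour narrower RING1B peaks. Widths of these midpoint classes were not compared, so that value did not decide the question. Reading only H3K27me3 at the midpoint left 3.72 points (0.993 to 6.76). The classes, still set by any overlap, differed in median width (3171 against 728 bp), so this value did not decide the question either. Pairs matched on RING1B enrichment (8.16 points, 3.90 to 12.4) decided nothing, since the medians were 2.95 and 2.85 and the matching moved none of 7 differences outside its interval. The hypothesis that AUTS2 marks RING1B promoters with less H3K27me3 stays open, with -23.4 points (-28.4 to -18.3) in 661 width-matched pairs that all had H3K4me3, which 1 library per antibody cannot separate from differences in antibody or cell type.

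Some of the 1635 brain AUTS2 peaks in no other list could be weak calls near the floor of the caller, since they made up 47.4% of the 10% of AUTS2 peaks with the lowest enrichment and 0.364% of the 10% with the highest. The decline was gradual, with 28.3% still in no other list in the seventh of 10 bins by enrichment (median 3.75) and 15.9% in the eighth (4.40), above the floor of 2.5. A second account was that peaks of other lists ended just beside them. Most of the 1635 had no such neighbour within 1 kb, so at that distance the account does not cover them. The share within 1 kb was 12.6% (11.03 to 14.3), between the bounds set beforehand for accepting the account (50%) and rejecting it (10%). By that rule it stays undecided for the class as a whole. Among circularly shifted peaks that overlapped none, the share was 6.60% (4.78 to 8.49 over 200 shifts), a reference corrected after the observed value was seen. Weak binding at sites with none of the 9 other features was not separated from false calls.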
